A study of Mus musculus with 31 samples.

How the data were processed

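Total liver RNA from male mice was measured on a mouse Affymetrix array that carries only perfect-match probes. The series held 31 arrays in 8 groups, and its labels call the arrays of a group biological replicates. Each group held 4 arrays except untreated Ire1 ko, which held 3. Per the submitters' processing notes, the deposited values were made with RMA (background correction, quantile normalization and median polish) and the affy package, with no versions given. The deposited unit was probe set intensity on a linear scale, rounded to whole numbers, and log2 of the intensity was taken before any test. Whether the 31 arrays were normalised in one run was not stated.

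The table held 45037 probe sets, and 0 of its columns were left unmapped to a sample. Its lowest value was 3, the median was 5 on every array, and 66.2% of values were 6 or less. The brightest value per array lay between 9367 and 24483. Between 19.8% and 23% of the probe sets of an array reached an intensity of 16. Near this floor the rounding to whole numbers made neighbouring values differ by large steps on the log2 scale, and fold changes of dim genes were compressed. The number of arrays also limits the precision. The number of identical pairs of arrays was 0, and correlations between arrays of a group lay between 0.9716 and 0.9911.

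The array annotation gave 1 gene symbol to 28898 probe sets and several symbols to 551. It did not hold 15588 probe sets. Each of the 17097 genes was represented by the probe set with the highest mean over the 31 arrays among those with exactly 1 symbol. Of these genes, 7180 had more than 1 probe set. No genome build is tied to the probe sets, and no coordinates were assigned to measured values. A gene table of the mouse genome served only to bring 16937 symbols to their current names and to order genes along chromosomes.

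Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p values were adjusted by Benjamini-Hochberg over the genes tested at a threshold of 0.05. A gene was tested when its probe set lay above the 30th percentile of its array in at least 3 arrays of the fit. The Xbp1 ko arrays and their WT littermates formed one fit of 8 arrays, and the siRNA arrays another fit of 8 arrays. The Ire1 experiment formed a fit of 15 arrays and 4 groups, from which the genotype contrasts, the tunicamycin contrasts and their interaction were taken. Tests of single genes were two-sided, and a log2 fold change is given with its standard error (SE). Levels are given as mean intensity with the standard deviation (SD) over the arrays of a group. Overlaps of called genes were tested with one-sided Fisher's exact tests across genes, which are not independent replicates. The expected counts take every tested gene as equally likely to be called. Bright genes were called more often: a group mean intensity of 16 was reached by 337 of 380 genes called in Xbp1 ko, against 5624 of 14010 tested. The expected counts therefore tend to be too low and the p values too small. Contrasts within the Ire1 experiment also share the same estimate of spread for each gene, which can raise the overlaps between them.

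Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 39 lists of a comparison. The 39 lists, with 897 genes, covered the endoplasmic reticulum (ER), stress signalling, liver metabolism, plasma proteins and markers of liver and other cell types. Camera was repeated with an estimated correlation, and fry of limma gave a directional test that does not compare a list with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. The list of carboxylesterases held genes that the study chose on these samples, so it is not independent evidence of its own direction, and 1 further listed gene is not reported here.

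The genes named for each comparison were Xbp1 and Ern1, the 8 called genes with the highest and the 8 with the lowest fold change whose arrays did not overlap between the groups, and up to 4 members of each list described. For the interaction, the condition on overlap was left out. The carboxylesterases were named throughout, and 12 genes were named for each overlap of comparisons. The tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Shifting each array to a common median over brighter probe sets, a filter at an intensity of 16, the exchange of the siRNA group labels, the alternatives and splits for 2 further overlaps and 2 further gene lists were chosen after seeing the data.

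The fits were tested on simulated data with 200 changed genes in each of 10 simulations, rounded as the deposited values were. All changed genes were drawn from those with a mean of 16 or more. Recovery is therefore known for bright genes only, and every simulated call of a dimmer gene was false by construction. In the 8-array fits 15.8% (Xbp1) and 14.5% (siRNA) of the calls were false. Without rounding these shares were 4.6% and 4%. Among genes with a mean of 16 or more they were 2.1% and 2.4%. In the 15-array fit the share lay between 3.2% and 5.4%. A 4-fold change was recovered in at least 97.3% of cases in every comparison. A 2-fold change was recovered in 78.1% of cases in the Xbp1 comparison and in 63% for the interaction.

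Alternatives covered quantile normalization and a common median, the filter, the choice of probe set, the variance model, array weights, one fit over all 31 arrays, a 2-fold threshold, the replicate number as a block, and leaving out each array in turn. No array was left out of the reported values. Probe sets with several symbols or none were tested apart from the genes.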

Results

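Gene expression was measured in the liver of male mice labelled as knockouts (ko) of Xbp1 or Ire1. XBP1 is a transcription factor of the unfolded protein response. IRE1α is the ER sensor that splices the Xbp1 mRNA and can cleave other mRNAs. IRE1α is encoded by Ern1. The 31 arrays formed 8 groups from 3 experiments. The first compared Xbp1 ko mice with WT littermates at 14 weeks of age, with 4 arrays each. In the second, Xbp1 ko mice aged 9 weeks were sampled 8 days after injection of siRNA against luciferase, a control target, or against IRE1, with 4 arrays each. The last compared WT and Ire1 ko mice at 14 weeks, untreated or 6 h after 2 mg/kg tunicamycin, a drug that blocks N-glycosylation and so causes ER stress. It held 4 arrays per group except untreated Ire1 ko, with 3. The labels give the strain of the Ire1 ko mice as mixed and that of the WT mice as C57BL/6, but also call the untreated WT mice littermates of the Ire1 ko mice. If the strain labels hold, strain and Ire1 genotype cannot be told apart. The study set out to find mRNAs cleaved through IRE1 and genes controlled by XBP1. The number of arrays limits the precision of every value below, which is an intensity or a log2 ratio of intensities.

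**Figure D1:**
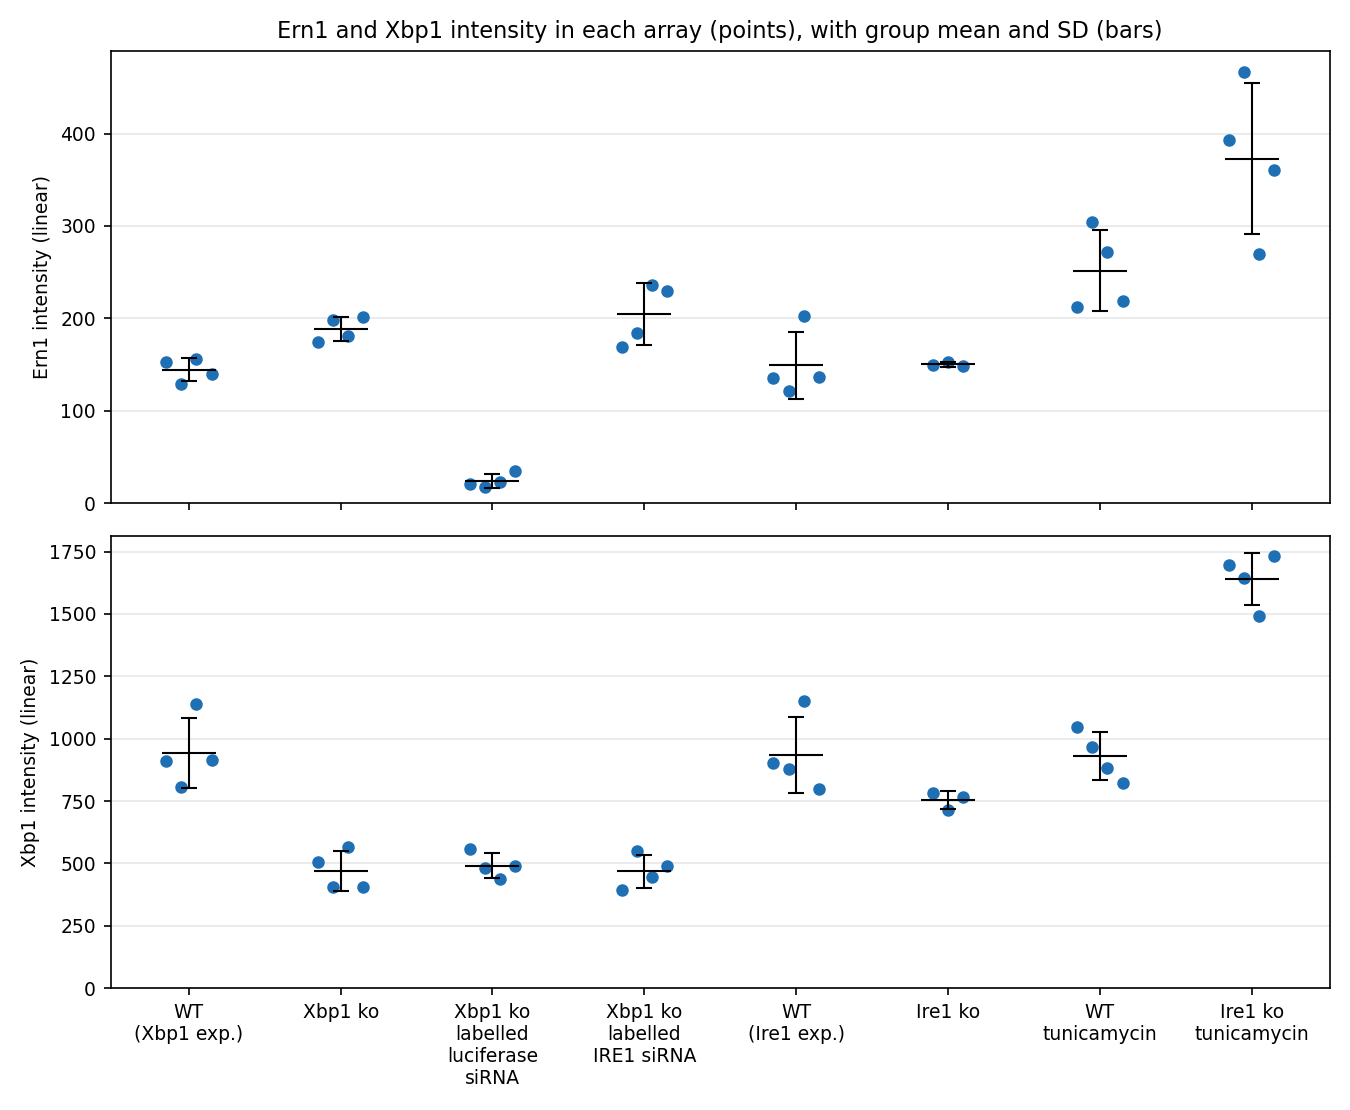
Intensity of Ern1 and Xbp1, each on the probe set used for the gene, on each of the 31 arrays, by group as labelled. Points are arrays and horizontal lines are group means. Ern1 averaged 24.25 in the arrays labelled luciferase siRNA and 204.8 in those labelled IRE1 siRNA.

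The comparison of Xbp1 ko with WT liver asked which genes depend on XBP1. Xbp1 itself averaged 943.8 ± 140 (SD, n = 4) in WT and 470 ± 80.3 (SD, n = 4) in Xbp1 ko, a log2 change of -1.01 (SE 0.14; adjusted p = 0.00866). Which part of the transcript is deleted is not known here, so this value does not measure the loss of the protein. Ern1 had a log2 difference of 0.39 (SE 0.09; adjusted p = 0.0622). The lowest genes included carboxylesterases, which hydrolyse ester-containing lipids and drugs. Ces1g fell from 285 ± 36.2 to 16.25 ± 4.27 and Ces1e from 155 ± 32.1 to 11.25 ± 6.55 (SD, n = 4 each). Tmem238 fell from 208.5 ± 15.5 to 16.75 ± 4.19, and Bloc1s1, a long-known substrate of IRE1 cleavage, from 147.2 ± 16.1 to 22.25 ± 2.99. Hgsnat, a lysosomal enzyme of heparan sulfate breakdown, and Cnmd were lower by log2 changes of -2.66 (SE 0.27) and -2.52 (SE 0.26). Cav1, the main protein of caveolae, rose from 6.75 ± 0.957 to 77.25 ± 18.3, a log2 change of 3.50 (SE 0.18; adjusted p = 7.47e-05).

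Camera passed 5 lists of the secretory pathway in Xbp1 ko, of which ER translocation alone held with an estimated correlation. Of 19 measured genes for translocation into the ER, 11 fell and 0 rose (13 fell when adjusted over the list alone; camera adjusted p = 9.44e-19), among them Sec61b, a subunit of the translocation channel, by a log2 change of -1.35 (SE 0.09), and Tram1 at -0.97. With an estimated correlation its adjusted p = 0.0371 stayed below 0.05. Of 27 ER chaperones and folding enzymes, 12 fell (18 adjusted over the list alone), including Erp44 at -1.81 (SE 0.08), Hyou1 at -1.41 and P4hb at -0.95. Camera gave 1.1e-22, and the adjusted p = 0.107 with an estimated correlation. For N-glycosylation 9 of 28 fell (12 adjusted over the list alone), with Uggt1 at -1.45 and Rpn1 at -1.35, and the adjusted p = 0.114 with an estimated correlation. In ER to Golgi transport 13 of 37 fell, with Lman2 at -0.73 and Surf4 at -0.69, against 21 lower and 1 higher adjusted over the list alone. There the adjusted p = 0.107 with an estimated correlation. Of 18 genes for degradation of ER proteins 5 fell, also 5 adjusted over the list alone, among them Edem2 at -1.18 and Os9 at -0.66 (adjusted p = 0.273 with an estimated correlation and 0.0995 by fry).

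Of 19 cholesterol synthesis genes, 14 fell (19 adjusted over the list alone; camera adjusted p = 2.85e-26), with Fdps at -1.60 (SE 0.17) and Sc5d at -0.82. The call held at an adjusted p = 0.0371 with an estimated correlation. In lipogenesis 6 of 25 fell (7 adjusted over the list alone). Dgat2, which makes triglyceride, fell from 1078 ± 30.7 to 270.5 ± 48.4 (SD, n = 4), and Fads1 fell by 1.43 on the log2 scale. The adjusted p = 0.487 with an estimated correlation for this list. All 5 measured carboxylesterases fell, also 5 adjusted over the list alone, with Ces1d at -2.89, Ces1f at -2.46 and Ces1c at -2.19. This list holds genes chosen by the study on these samples and is not independent evidence, and its adjusted p = 0.0492 with an estimated correlation. The carboxylesterases are close paralogs, so how far each probe set reads a single one is uncertain. Of 40 secreted plasma proteins, 10 fell (17 adjusted over the list alone), with the complement component Hc at -1.68 (SE 0.10) and the anticoagulant Proc at -1.59 (SE 0.07). The adjusted p = 0.107 with an estimated correlation. Of 24 genes of fatty acid oxidation 3 rose (8 higher and 1 lower adjusted over the list alone), with a list median of 0.17. The adjusted p = 0.487 with an estimated correlation, and Decr1, at 0.29, lost its call in one fit over all 31 arrays and when probe sets were averaged.

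Among 10 published IRE1 substrates 3 fell, namely Bloc1s1, Hgsnat and Tapbp (-1.25), while the list itself missed the camera threshold (adjusted p = 0.0539). Among 34 measured genes downstream of PERK and ATF4, another arm of the stress response, limma called 0, with 5 higher at an unadjusted p under 0.05, and the camera adjusted p was 0.0672. Markers of stellate cells and fibroblasts had a median of 0.27, with 0 of 15 called by limma, 3 higher at an unadjusted p under 0.05 and a camera adjusted p = 0.0331 (adjusted p = 0.487 with an estimated correlation). Col1a1 stood at 0.59 (adjusted p = 0.112). Camera also passed periportal genes (median -0.06; 0 of 11 called by limma, 1 lower adjusted over the list alone and 3 unadjusted; adjusted p = 0.181 with an estimated correlation) and ribosomal proteins (median 0.06; 1 of 29 called, Rpl10 at -0.33; adjusted p = 0.487 with an estimated correlation). The p53 list passed with 1 of 15 called, Cdkn1a at 2.20 (adjusted p = 0.273 with an estimated correlation). Of 13 lymphocyte markers Cd79b alone was called, at 0.37, a gene named after its value was seen, against 2 adjusted over the list alone. For markers of Kupffer, endothelial, cholangiocyte, neutrophil, erythroid, adipose and pancreatic cells limma called 0, with at most 1 member per direction at an unadjusted p under 0.05 (Kupffer 1 higher and 1 lower adjusted over the list alone). For this and the later comparisons, where no count adjusted over the list alone is given beside a list, it equalled the count over all genes.

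In all, limma called 380 of 14010 genes between Xbp1 ko and WT, 90 higher and 290 lower. The split was 122 and 316 after quantile normalization, and 155 and 354 with a common median over brighter probe sets. At least a 2-fold change was found for 11 of the higher and 106 of the lower genes. A group mean of 16 or more, a limit chosen after seeing the data, was reached by 337 of the called genes (71 higher, 266 lower). The other 43 lay near the floor where simulated false calls were frequent. The simulations changed no dim gene, so they give no share of true calls there. Without WT replicate 1 the count was 237 (46 higher, 191 lower), of which 222 were among the 380. Several high genes were called on the full set but not without single arrays: Adgrv1 (2.05), Cdkn1a, Vnn1 (1.83), Cyp7a1 (1.75) and Tpm2 each lost the call in 7 of the 8 fits that left out 1 array.

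The siRNA comparison asked what the loss of IRE1α changes in Xbp1 ko liver. The values of Ern1 on its brightest probe set, the one used here, contradict the group labels. Its other probe sets lay near the floor, at 12 or less in these arrays, and did not separate the groups. On the probe set used, Ern1 lay between 18 and 35 in the 4 arrays labelled luciferase siRNA. It lay between 169 and 236 in the 4 arrays labelled IRE1 siRNA. The mean was 24.25 ± 7.46 against 204.8 ± 33.3 (SD, n = 4 each), a log2 difference of 3.11 (SE 0.22; adjusted p = 0.000726). In Xbp1 ko mice without siRNA it lay between 175 and 201. Directions are therefore given as labelled, with the arrays labelled IRE1 minus those labelled luciferase, and every direction turns round if the labels are exchanged. Xbp1 had a log2 difference of -0.07 (adjusted p = 0.78).

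The lowest genes in the arrays labelled IRE1 siRNA included several that fell in Xbp1 ko. Ces1g averaged 10.5 ± 4.04 against 94.75 ± 43.6 in the arrays labelled luciferase, Tmem238 9.5 ± 1 against 67 ± 24.2, and Bloc1s1 20.75 ± 2.22 against 107 ± 18.4 (SD, n = 4). Dgat2 averaged 231 ± 38.7 against 909.2 ± 122. St3gal3, a sialyltransferase, and the phosphatase Ptprf had log2 changes of -2.14 (SE 0.13) and -1.99 (SE 0.13), and Hgsnat -2.05 (SE 0.21). Of the genes higher as labelled, Slc3a2, a chain of amino acid transporters, had 0.94 (SE 0.10; adjusted p = 0.00518), Rcc2 0.77 and Adgrv1 1.87 (SE 0.25; adjusted p = 0.0118). All 5 measured carboxylesterases were lower, also 5 adjusted over the list alone, a list that is not independent of these samples, with Ces1f at -1.87 and Ces1c at -1.75. The adjusted p = 0.172 with an estimated correlation. Leaving out 1 array ended the call of Ces1d (-1.80) in 6 of 8 cases, all but those without replicates 1 and 4 of the arrays labelled luciferase, with an adjusted p up to 0.1. For Ces1e (-2.02) it did so in 5 of 8 cases.

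Of 40 secreted plasma proteins 14 were lower (20 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.58e-17), with Hc at -1.51, Afm at -1.43 and Proc at -1.40 (SE 0.10). The adjusted p = 0.172 with an estimated correlation. Bloc1s1, Hgsnat and Tapbp (-1.18; SE 0.12) were the 3 lower genes among 10 published IRE1 substrates, also 3 adjusted over the list alone, with an adjusted p = 0.286 with an estimated correlation. For cholesterol synthesis 2 of 19 genes were lower, Fdps (-1.50) and Tm7sf2 (-0.72), each losing its call in 7 of 8 fits that left out 1 array, against 16 adjusted over the list alone. The adjusted p = 0.23 with an estimated correlation. In lipogenesis 3 of 24 were lower, with Agpat3 at -0.57, against 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). ER translocation genes had a median of 0.08, or 0.03 with a common median over brighter probe sets, and 0 of 19 called by limma, 4 of them higher at an unadjusted p under 0.05 (camera adjusted p = 0.0237; adjusted p = 0.335 with an estimated correlation). Sec61b stood at 0.27 (SE 0.07; adjusted p = 0.123). ER chaperones were lower for 2 of 27, with Erp44 at -1.0 (SE 0.11), against 4 adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). PERK and ATF4 genes were higher for 4 of 35, among them Slc3a2 and Slc7a5 (0.26), against 9 adjusted over the list alone, with an adjusted p = 0.321 with an estimated correlation. Respiratory chain genes were higher for 1 and lower for 2 of 32, with Ndufa9 at -1.32, against 14 higher and 2 lower adjusted over the list alone (adjusted p = 0.172 with an estimated correlation).

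Camera passed 5 further lists in the siRNA comparison. For the acute phase 3 of 25 genes were lower, among them Itih4 at -1.37 and Fgg at -0.47, against 4 adjusted over the list alone, with an adjusted p = 0.496 with an estimated correlation. For pericentral genes 2 of 12 were lower, Cyp1a2 and Cyp2e1, with an adjusted p = 0.531 with an estimated correlation. Kupffer cell markers had a median of 0.28 and stellate cell markers 0.27, limma calling 0 of 17 and 0 of 14, with 3 and 5 higher at an unadjusted p under 0.05. Their adjusted p = 0.817 and 0.753 with an estimated correlation. Proteasome genes had a median of 0.08 with 0 of 29 called by limma, 1 higher adjusted over the list alone, 5 higher unadjusted, and an adjusted p = 0.515 with an estimated correlation. The other cell type lists had 0 members called by limma, with at most 3 per direction at an unadjusted p under 0.05.

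Between the siRNA groups limma called 253 of 14031 genes, 91 higher and 162 lower as labelled, and 213 of them (73 higher, 140 lower) reached a group mean of 16. A change of at least 2-fold was found for 2 of the higher and 60 of the lower genes. The balance moved with the scaling, to 66 higher and 197 lower after quantile normalization and to 49 and 256 with a common median over brighter probe sets. It was 54 and 150 without replicate 1 and 55 and 135 without replicate 3 of the arrays labelled luciferase. Erp44, Ndufb5, Atp5o and Fads2 lost the call when all probe sets of a gene were averaged.

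The overlap of the Xbp1 and siRNA comparisons was meant to find mRNAs cleaved by IRE1α, since such mRNAs would be lower in Xbp1 ko and would return when IRE1α is removed. Of 289 genes lower in Xbp1 ko and tested in both, 0 were among the 90 higher in the arrays labelled IRE1 siRNA (1.95 expected by chance; limma, 36 genes at unadjusted p under 0.05 in both). Leaving out 1 array gave 1 gene without replicate 4 of the arrays labelled luciferase, 1 without replicate 2 and 2 without replicate 4 of those labelled IRE1. In the opposite direction 104 of the 289 were among the 156 lower as labelled (3.39 expected; Fisher's exact p = 3.78e-141), which are the genes that return if the labels are exchanged. The 12 of these with the largest changes were Ces1g, Tmem238, Bloc1s1, St3gal3, Hgsnat, Ces1e, Dgat2, Ptprf, Ces1f, Gjb1, Ces1d and Tex264. Another 10 genes were higher in both comparisons (0.608 expected; Fisher's exact p = 4.38e-10). Across the 13317 genes tested in both, which are not independent, the log2 changes had a Pearson correlation of 0.513 and a Spearman correlation of 0.285.

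**Figure D2:**
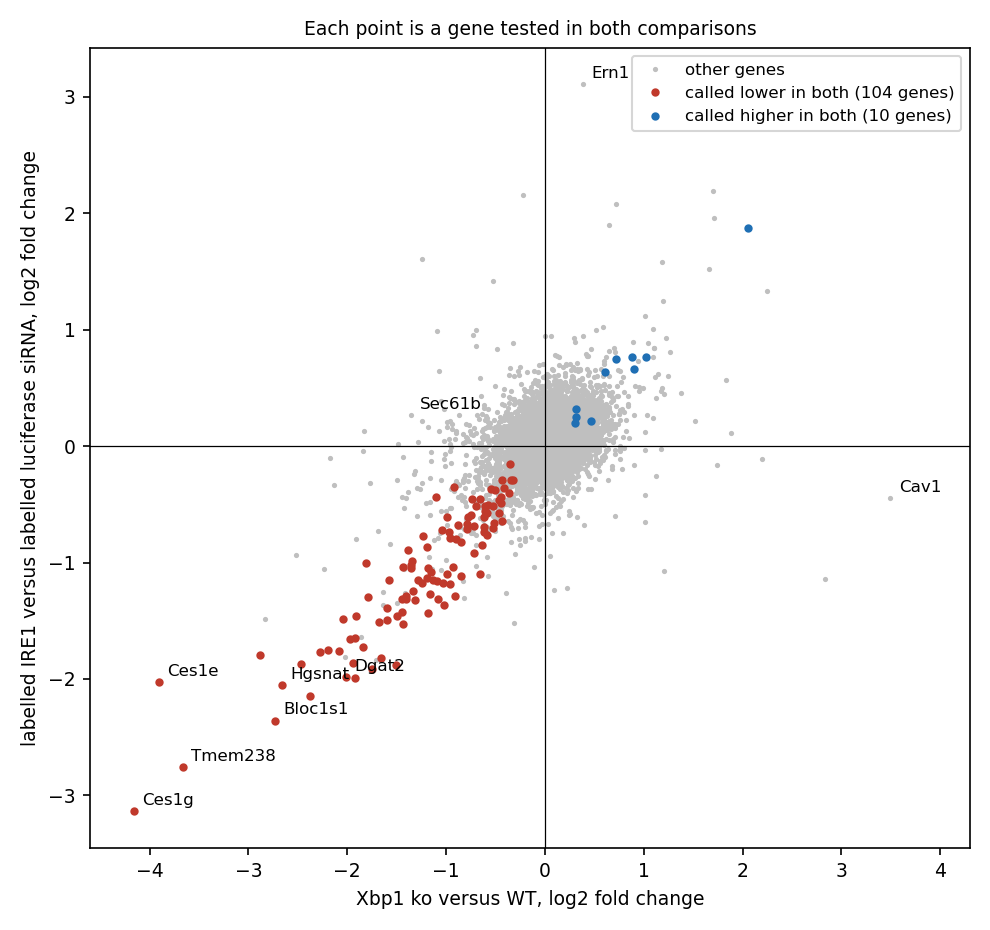
Log2 fold change in Xbp1 ko versus WT (horizontal) against the arrays labelled IRE1 siRNA versus those labelled luciferase siRNA (vertical), with 1 point per gene tested in both. Red points are the 104 genes lower in both and blue points the 10 higher in both. Sec61b lies at -1.35 and 0.27, and Ces1g at -4.16 and -3.14.

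In untreated liver the comparison of Ire1 ko with WT asked what depends on IRE1α without added stress. Ern1 averaged 149.2 ± 36.6 (SD, n = 4) in WT and 150.3 ± 2.52 (SD, n = 3) in Ire1 ko (log2 difference 0.04; adjusted p = 0.958). The deleted part of the gene is not known here, so this probe set gives no check of the knockout. Xbp1 had a log2 difference of -0.29 (SE 0.11; adjusted p = 0.372). Sec61b fell from 463.2 ± 65.6 to 155.3 ± 18, a log2 change of -1.57 (SE 0.13; adjusted p = 8.29e-06). Gmppb, which makes GDP-mannose, and the cargo protein Tmed3 fell by 1.85 (SE 0.21) and 1.81 (SE 0.22) on the log2 scale. The largest rise was that of Bcl6, a transcriptional repressor, from 13 ± 4.83 to 105.7 ± 19.2 (log2 3.07; SE 0.31; adjusted p = 5.02e-05). Rgs16, a regulator of G protein signalling, rose by 1.71 (SE 0.24) and Cav1 by 0.87 (SE 0.13), the latter losing its call in one fit over all 31 arrays. Cish, a target of cytokine and growth hormone signalling, fell by 1.62 (SE 0.22) and the hepatocyte factor Onecut1 by 1.69 (SE 0.24).

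Genes of the secretory pathway were lower in untreated Ire1 ko as well. Of 19 ER translocation genes 14 fell (15 adjusted over the list alone; camera adjusted p = 1.15e-34), with Spcs2 at -1.20 and Ssr1 at -0.90, and the call held at an adjusted p = 0.000529 with an estimated correlation. N-glycosylation fell for 13 of 28 genes (17 adjusted over the list alone), including Ostc at -1.43 and Ddost at -1.06, at an adjusted p = 0.00245 with an estimated correlation. ER chaperones fell for 11 of 27 (21 adjusted over the list alone), with Hyou1 at -1.38 and P4hb at -0.95, also at an adjusted p = 0.00245 with an estimated correlation. In ER to Golgi transport 12 of 37 fell (25 adjusted over the list alone), with the coat proteins Sec23b at -1.22 and Sec24d at -1.09 (adjusted p = 0.00958 with an estimated correlation). Degradation of ER proteins fell for 2 of 18, Selenos at -0.69 and Edem1 at -0.49, against 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.0313 with an estimated correlation). For cholesterol synthesis 5 of 19 fell (17 adjusted over the list alone; adjusted p = 0.0342 with an estimated correlation). Among them Lss, at -1.25, was not called without replicate 1 or replicate 3 of untreated Ire1 ko, and Fdps, at -0.74, not without replicate 3 (adjusted p = 0.0673).

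Of the 5 carboxylesterases limma called 0 between untreated Ire1 ko and WT, with 1 lower at an unadjusted p under 0.05 (median 0.26; camera adjusted p = 0.482), with Bloc1s1 at 151.2 ± 6.95 in WT (SD, n = 4) and 191.7 ± 21 in Ire1 ko (SD, n = 3). Other lists passed camera with few or no called members. For pericentral genes only Rhbg, an ammonia transporter, was called, at 1.48, with an adjusted p = 0.417 with an estimated correlation and no call in 4 of 7 fits that left out 1 array. Gluconeogenesis had a median of 0.19 with 0 of 14 called by limma, 1 higher adjusted over the list alone and 4 unadjusted (adjusted p = 0.149 with an estimated correlation). Fatty acid oxidation (0.09), NF-κB targets (0.18), secreted plasma proteins (0.05) and NRF2 targets (0.08) had 0 called by limma, with 4, 2, 2 and 2 higher unadjusted and, for NRF2, 1 higher adjusted over the list alone. Each had an adjusted p = 0.592 with an estimated correlation. Respiratory chain genes had a median of 0.10 with 0 of 32 called by limma, 2 higher unadjusted, and an adjusted p = 0.315 with an estimated correlation. Cell type lists had 0 members called by limma, with at most 1 per direction at an unadjusted p under 0.05.

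Limma called 143 of 15172 genes between untreated Ire1 ko and WT, 12 higher and 131 lower, and 132 of them reached a group mean of 16. The split was 21 and 116 after quantile normalization, and 28 and 122 with a common median over brighter probe sets. Without WT replicate 4 it was 24 and 123, without replicate 2 of untreated Ire1 ko 7 and 97, and without its replicate 3, with replicate 2 kept, 14 and 82. Of the genes lower here, 62 were also lower in Xbp1 ko (2.74 expected; Fisher's exact p = 3.39e-70). By the strain labels, which the littermate label of the untreated WT mice contradicts, strain differs along with genotype in this comparison and in that after tunicamycin.

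Tunicamycin in WT mice asked for the response of the liver to ER stress. The sample titles name no vehicle control for the untreated mice of either genotype. Effects of the drug therefore cannot be told apart from those of giving it. Ern1 rose by 0.77 (SE 0.17; adjusted p = 0.00217), a call lost when its probe sets were averaged (0.17). Xbp1 had a log2 difference of 0.00 on its probe set. The stress factor Ddit3, also known as CHOP, rose from 14.75 ± 2.99 to 3733 ± 367 (SD, n = 4), and Atf3 from 5.25 ± 0.5 to 1150 ± 280. Nupr1, Trib3 and the hormone Fgf21 had log2 changes of 7.77, 6.38 and 6.40, and Derl3, a factor of ER protein degradation, 6.26. Keg1 fell from 952.8 ± 171 to 14.5 ± 5.07, while Igfals, which binds growth factors in plasma, and the repressor Nr0b2 had log2 changes of -5.01 and -4.57. Several of these genes lay at the floor in 1 group, so their fold changes are compressed.

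ER genes rose as groups. Chaperones rose for 25 of 27 genes, also 25 adjusted over the list alone, with Hspa5, the main ER chaperone, from 962 ± 156 to 3811 ± 174 (SD, n = 4) and Pdia4 from 205 ± 55.9 to 2046 ± 101 (adjusted p = 0.00697 with an estimated correlation). Degradation of ER proteins rose for 16 of 18, with Syvn1 at 3.75 and Sel1l at 3.47 (adjusted p = 0.00532 with an estimated correlation). For PERK and ATF4 targets 27 of 37 rose and 2 fell, with the serine synthesis gene Psat1 at 5.71, against 27 higher and 4 lower adjusted over the list alone (adjusted p = 5.24e-05 with an estimated correlation). ER translocation rose for 18 of 19 and fell for 1 (adjusted p = 0.0105 with an estimated correlation), N-glycosylation rose for 20 of 28 and fell for 1, with Gfpt1 at 4.12 (22 higher and 1 lower adjusted over the list alone), and ER to Golgi transport rose for 33 of 37 and fell for 2, with Kdelr3 at 2.89. The adjusted p was 0.0274 with an estimated correlation for both.

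Of 40 secreted plasma proteins 29 fell, with the coagulation factor F7 at -1.77, against 32 lower and 1 higher adjusted over the list alone (adjusted p = 0.0335 with an estimated correlation). Lipoprotein genes fell for 18 of 26 and rose for 2, with the sterol exporters Abcg8 at -3.84 and Abcg5 at -3.04 (adjusted p = 0.00922 with an estimated correlation). The 5 carboxylesterases fell, a list not independent of these samples, Ces1d from 758.5 ± 279 to 18.5 ± 9.75, also 5 adjusted over the list alone, with an adjusted p = 0.117 with an estimated correlation. Published IRE1 substrates fell for 4 of 10, with Bloc1s1 at -3.15 (SE 0.17), Hgsnat at -1.34, Tapbp at -0.90 and Sparc at -0.46 (adjusted p = 0.166 with an estimated correlation). The following lists passed camera and not the test with an estimated correlation. Fatty acid oxidation fell for 19 of 24 and rose for 2, with Ppara at -2.84 (20 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Bile acid genes fell for 15 of 23 and rose for 2 (16 and 3 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), and drug metabolism fell for 15 of 26 (16 adjusted over the list alone; adjusted p = 0.231 with an estimated correlation), while Cyp2b10, its 1 rising member, changed by 4.63. Lipogenesis fell for 11 of 25 and rose for 1 (adjusted p = 0.275 with an estimated correlation) and cholesterol synthesis for 10 of 19, 4 of the 19 rising (adjusted p = 0.576 with an estimated correlation). Interferon-induced genes fell for 18 of 30, with Iigp1 at -3.39 (adjusted p = 0.231 with an estimated correlation). Respiratory chain genes fell for 29 of 32, with Ndufa9 at -0.87 (adjusted p = 0.102 with an estimated correlation), and ribosomal proteins rose for 13 of 29, with Rpl12 at 0.86 (15 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation).

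Zonation, male-biased and Kupffer lists passed camera for tunicamycin in WT liver, and none of these held with an estimated correlation. Periportal genes fell for 8 of 11 and rose for 1, with Hal at -3.37 (adjusted p = 0.0651 with an estimated correlation), pericentral genes for 6 of 12 (adjusted p = 0.366 with an estimated correlation) and male-biased genes for 7 of 11 (8 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation). Kupffer cell markers fell for 7 of 17, with Slc40a1 at -1.61 and Cd5l at -1.14 (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.631 with an estimated correlation). Endothelial markers fell for 7 and rose for 1 of 17 (camera adjusted p = 0.072), stellate markers fell for 4 of 15 (0.109), lymphocyte markers for 2 of 13 (0 adjusted over the list alone), erythroid markers for 2 of 4 and pancreatic markers for 2 of 11 (1 adjusted over the list alone). Of 7 cholangiocyte markers Pkhd1 rose, at 1.58, a gene named after its value was seen. Neutrophil and adipose lists had 0 called by limma, with at most 1 per direction at an unadjusted p under 0.05. Lists that missed camera held large single changes in both directions. The clock genes, 5 higher and 6 lower of 18 (camera adjusted p = 0.819), included Arntl at 4.32 (SE 0.21) and Hlf at -2.19, and the labels give no time of day. Acute phase genes were 5 higher and 6 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.758), with the iron hormone Hamp at 1.39. NF-κB targets were 5 higher and 4 lower, p53 targets 5 and 5, with Cdkn1a at 5.58, cell cycle genes 5 and 5 (5 and 7 adjusted over the list alone), NRF2 targets 4 and 9, gluconeogenesis genes 4 and 6 and proteasome genes 4 and 6.

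Limma called 5485 of 15172 genes for tunicamycin in WT mice, 2803 higher and 2682 lower, of which 1138 and 812 changed at least 2-fold. The balance turned with the scaling, to 2520 higher and 3196 lower after quantile normalization and to 2620 and 2987 with a common median over brighter probe sets. A group mean of 16 was reached by 4240 of them. Leaving out 1 array gave between 5056 and 5234 genes.

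Tunicamycin in Ire1 ko mice asked for the part of this response that runs without IRE1α. Here Xbp1 rose from 754.7 ± 35.6 (SD, n = 3) to 1640 ± 106 (SD, n = 4), a log2 change of 1.12 (SE 0.11; adjusted p = 1.15e-06), and Ern1 rose by 1.28 (SE 0.19). Atf3, Ddit3 and Trib3 rose by 7.11, 6.63 and 6.43, and Keg1 and Igfals fell by 6.37 and 4.44 on the log2 scale. Chaperones rose for 23 of 27 and fell for 1, with Manf at 3.68 (adjusted p = 0.0174 with an estimated correlation). Degradation of ER proteins rose for 14 of 18 and fell for 1, with Syvn1 at 3.09 (15 higher and 3 lower adjusted over the list alone; adjusted p = 0.0213 with an estimated correlation), and PERK and ATF4 targets rose for 27 of 37 and fell for 1, with Psat1 at 3.74 (28 and 1 adjusted over the list alone; adjusted p = 2.64e-05 with an estimated correlation). Lipoprotein genes fell for 16 of 26 and rose for 3, with Abcg8 at -3.23 (18 and 3 adjusted over the list alone; adjusted p = 0.0174 with an estimated correlation). ER translocation, with 6 of 19 higher and 2 lower and a median of 0.09 (7 and 4 adjusted over the list alone; camera adjusted p = 0.322), and ER to Golgi transport, with 9 of 37 higher and 5 lower and a median of 0.04 (11 and 6 adjusted over the list alone; camera adjusted p = 0.638), did not pass. Of the carboxylesterases Ces1f (-1.89), Ces1d (-1.49) and Ces1e (-1.02) fell, Ces1d losing its call in 4 of 7 fits that left out 1 array, while Ces1c stood at -0.12 and Ces1g at -1.47 (adjusted p = 0.155). That list is not independent of these samples and had an adjusted p = 0.344 with an estimated correlation.

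Further lists passed camera only at the preset correlation. N-glycosylation rose for 14 of 28 and fell for 3, with Gfpt1 at 3.59, ribosomal proteins rose for 22 of 29 (23 adjusted over the list alone), and proteasome genes fell for 17 of 29 and rose for 3, with Psmd2 at -0.77. Fatty acid oxidation fell for 15 of 24 and rose for 1 (17 and 1 adjusted over the list alone), interferon-induced genes fell for 12 of 30, pericentral genes for 6 of 12 and periportal genes for 5 of 11, with 1 rising. Each of these 7 lists had an adjusted p = 0.315 with an estimated correlation. Secreted plasma proteins fell for 22 of 40 and rose for 3 (25 and 3 adjusted over the list alone; adjusted p = 0.138 with an estimated correlation), respiratory chain genes fell for 19 of 32 (25 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation) and cholesterol synthesis genes for 9 of 19, with 4 rising (adjusted p = 0.597 with an estimated correlation). Bile acid genes fell for 13 of 23 and rose for 4, and drug metabolism fell for 10 of 26 and rose for 2, both with an adjusted p = 0.382 with an estimated correlation. Lists that missed camera but moved in part were lipogenesis (4 higher, 7 lower of 25; 5 and 7 adjusted over the list alone), gluconeogenesis (4 higher, 6 lower of 14), p53 targets (6 higher, 3 lower of 16; 6 and 4 adjusted over the list alone), NRF2 targets (3 higher, 6 lower of 19; 4 and 6 adjusted over the list alone), clock genes (5 higher, 3 lower of 18; 5 and 4 adjusted over the list alone) and male-biased genes (5 lower of 11). Published IRE1 substrates fell for 2 of 10 in these Ire1 ko mice (camera adjusted p = 0.266), Bloc1s1 at -0.72 (SE 0.18) and Tapbp at -0.54 (SE 0.13), both named after their values were seen. Of the cell type markers Slc40a1 (Kupffer) stood at -0.68, Col3a1 (stellate) at -1.0 and Alas2 (erythroid) at -0.70, with Kdr and Fcgr2b lower and Stab1 higher among 17 endothelial markers, genes named after their values were seen.

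Limma called 4197 genes for tunicamycin in Ire1 ko mice, 2630 higher and 1567 lower. The split was 2044 and 2229 after quantile normalization, and 2140 and 2368 with a common median over brighter probe sets, which moved the median log2 change of all genes by -0.106. Small rises such as those of ribosomal proteins are to be read relative to that shift. Of the genes that rose in WT 1900 also rose in Ire1 ko (486 expected), and 1296 fell in both (277 expected), with a Pearson correlation of 0.811 and a Spearman correlation of 0.694 across genes. The log2 changes in Ire1 ko had a slope of 0.648 on those in WT over the 5485 genes called in WT. The tunicamycin contrasts share the estimate of spread of each gene, so the expected counts of their overlaps tend to be too low.

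After tunicamycin Ire1 ko was compared directly with WT, and the interaction tested whether the response itself differed. Ern1 was higher in Ire1 ko by 0.55 (SE 0.17; adjusted p = 0.0371), a call lost in 6 of 8 fits that left out 1 array, and its interaction of 0.52 was not called (adjusted p = 0.295). Xbp1 was higher by 0.82 (SE 0.10), with an interaction of 1.12 (adjusted p = 0.00017). Bhlha15, also known as Mist1, rose from 5 to 170.8 ± 17.2 (SD, n = 4) in WT and averaged 5.75 ± 0.957 in Ire1 ko after tunicamycin, an interaction of -4.90 (SE 0.18; adjusted p = 1.72e-10). Far1, which makes fatty alcohols, averaged 282.8 ± 160 in WT and 6 in Ire1 ko after tunicamycin, and Arfgap3, a regulator of Golgi transport, 113.8 ± 20.5 and 6.5 ± 0.577. Suco averaged 541.2 ± 23.5 and 40.5 ± 8.1. In the other direction Bloc1s1 fell to 17.5 ± 4.65 in WT and averaged 116.2 ± 13.7 in Ire1 ko, an interaction of 2.43 (SE 0.25; adjusted p = 1.26e-05). Ces1d averaged 18.5 ± 9.75 in WT and 392.5 ± 128 in Ire1 ko (interaction 4.04; SE 0.62; adjusted p = 0.000596), and Sgk1, a stress-responsive kinase, was higher in Ire1 ko by 2.91.

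**Figure D3:**
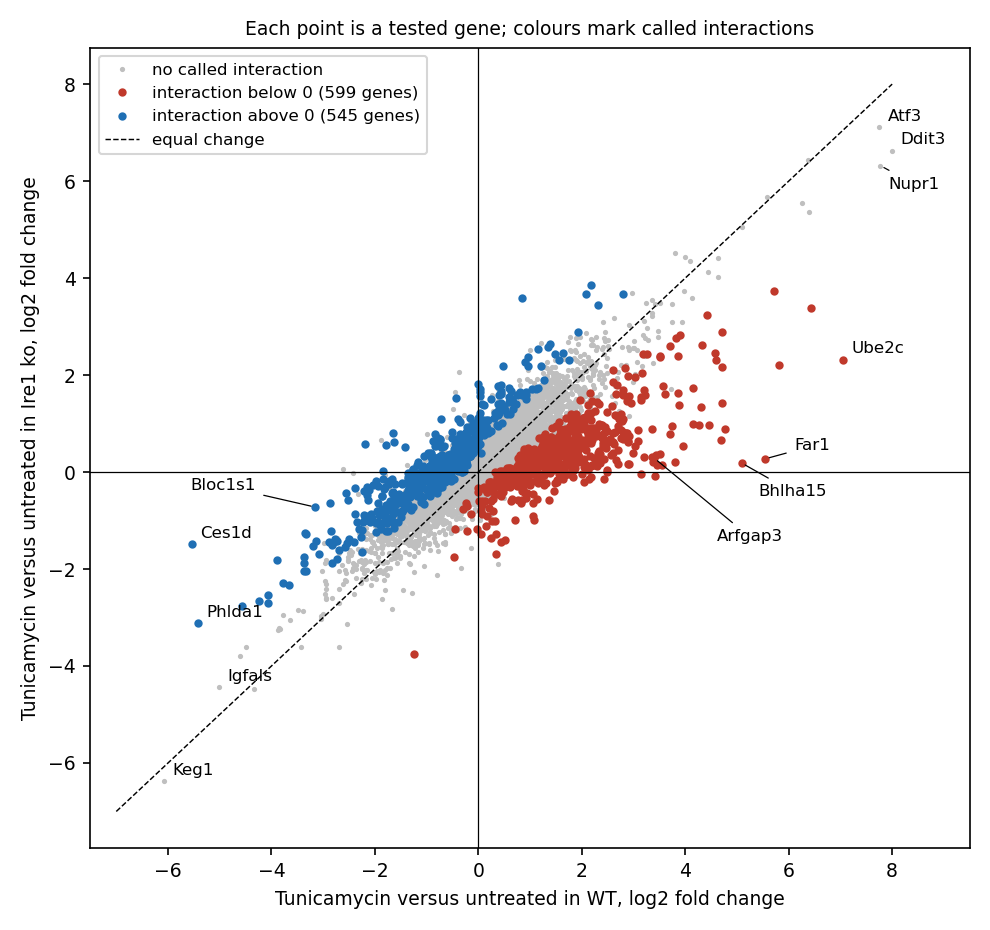
Log2 fold change 6 h after tunicamycin in WT (horizontal) and in Ire1 ko (vertical), with 1 point per tested gene and a dashed line of equal change. Coloured points are called interactions, 599 below 0 in red and 545 above 0 in blue. Bhlha15 changed by 5.09 in WT and Bloc1s1 by -3.15.

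Lists of secretory genes were lower in Ire1 ko than in WT after tunicamycin. In ER to Golgi transport 35 of 37 were lower in Ire1 ko than in WT, with Sec23b at -2.58 and Sec24d at -2.30 (adjusted p = 0.00134 with an estimated correlation), and 29 had a negative interaction (31 adjusted over the list alone; adjusted p = 0.0039 with an estimated correlation). ER translocation was lower for 18 of 19, with Sec61b at -2.99 (SE 0.12) and Ssr1 at -2.44 (adjusted p = 0.000757 with an estimated correlation), and 16 had a negative interaction (17 lower and 1 higher adjusted over the list alone; adjusted p = 0.00325 with an estimated correlation). Degradation of ER proteins was lower for 14 of 18 (adjusted p = 0.00134 with an estimated correlation), with 10 negative interactions (15 adjusted over the list alone; adjusted p = 0.0039 with an estimated correlation). N-glycosylation was lower for 21 of 28 and higher for 1, with Pgm3 at -3.33 and Gmppb at -3.26 (22 lower adjusted over the list alone; adjusted p = 0.00335 with an estimated correlation). It had 12 negative interactions (13 adjusted over the list alone; adjusted p = 0.0666 with an estimated correlation). Chaperones were lower for 18 of 27, with Fkbp11 at -3.57 (23 adjusted over the list alone; adjusted p = 0.00744 with an estimated correlation), while 8 had a negative and 2 a positive interaction (10 and 2 adjusted over the list alone; adjusted p = 0.379 with an estimated correlation). PERK and ATF4 targets were lower for 9 of 37 and higher for 1, with Aldh18a1 at -3.39 (adjusted p = 0.0131 with an estimated correlation), and 5 had a negative and 2 a positive interaction (7 and 2 adjusted over the list alone; adjusted p = 0.0598 with an estimated correlation).

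Genes higher in Ire1 ko after tunicamycin included 21 of 40 secreted plasma proteins (23 adjusted over the list alone), with Hc at 1.66 and Serpina6 at 1.16 (adjusted p = 0.0643 with an estimated correlation). All 5 carboxylesterases were higher, a list not independent of these samples, also 5 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Ces1g (2.50) was not called without replicate 3 of the Ire1 ko mice given tunicamycin (adjusted p = 0.0589), and Ces1e (0.71) lost its call in 4 of 8 fits. Of 10 published IRE1 substrates Bloc1s1 (2.77; SE 0.17), Hgsnat (1.29; SE 0.20) and Tapbp (0.60) were higher (adjusted p = 0.118 with an estimated correlation). Respiratory chain genes were higher for 16 of 32, with Ndufa9 at 0.72 (20 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), fatty acid oxidation for 11 of 24 with 1 lower (adjusted p = 0.387 with an estimated correlation), gluconeogenesis for 7 of 14 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation) and periportal genes for 6 of 11, with Hal at 1.37 (adjusted p = 0.0867 with an estimated correlation). Bile acid genes were higher for 8 of 23 with 1 lower (12 and 2 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), drug metabolism for 7 of 26 with 1 lower (adjusted p = 0.521 with an estimated correlation) and lipoprotein genes for 5 of 26 (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0604 with an estimated correlation). Cholesterol synthesis was lower for 7 of 19, with Mvd at -3.18 and Stard4 at -1.71 (8 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), and the proteasome for 8 of 29 with 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation). Lipogenesis (8 higher, 3 lower of 25; 9 and 3 adjusted over the list alone) and pericentral genes (3 higher, 1 lower of 12; 5 and 1 adjusted over the list alone) missed camera. Clock genes missed it as well (camera adjusted p = 0.373) with 6 higher and 3 lower of 18, among them Dbp at 2.08 and Arntl at -1.47. Among cell type markers only Slc40a1, at 0.88, and Pkhd1, at -1.39, were called, both named after their values were seen. The other cell type lists had 0 called by limma, with at most 3 per direction at an unadjusted p under 0.05.

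The interaction passed camera for 9 further lists, none of which held with an estimated correlation. Positive interactions were called for Ces1d, Ces1f (1.48), Ces1e (1.33) and Ces1c (0.86) in the list not independent of these samples (adjusted p = 0.187 with an estimated correlation). The call of Ces1f was lost in 9 of 15 and that of Ces1c in 6 of 15 fits that left out 1 array, and that of Ces1e without replicate 3 of untreated Ire1 ko (adjusted p = 0.059). Plasma proteins had 4 positive interactions, with Hc at 1.74 (5 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation), and lipogenesis 4 and bile acid genes 3 (5 adjusted over the list alone), each with an adjusted p = 0.461 with an estimated correlation. Lipoprotein genes had 3 (4 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), periportal genes 2 (4 adjusted over the list alone; adjusted p = 0.0789 with an estimated correlation) and respiratory chain genes 2 (adjusted p = 0.623 with an estimated correlation). Proteasome genes had 4 negative interactions (5 adjusted over the list alone; adjusted p = 0.327 with an estimated correlation). Endothelial markers had a median interaction of 0.27, with 0 of 17 called by limma, 3 higher unadjusted and an adjusted p = 0.623 with an estimated correlation.

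Limma called 2756 genes between Ire1 ko and WT after tunicamycin, 1469 higher and 1287 lower, and 1144 interactions, 545 positive and 599 negative. The interactions numbered 466 positive and 703 negative with a common median over brighter probe sets, 555 and 690 after quantile normalization, and 359 and 620 without replicate 3 of untreated Ire1 ko. Changes of at least 2-fold numbered 212 higher and 481 lower for the genotypes, and 191 and 327 for the interaction. A group mean of 16 was reached by 2350 genes of the first and 1009 of the second. Of the 131 genes lower in untreated Ire1 ko, 106 were also lower after tunicamycin (11.1 expected; Fisher's exact p = 2.84e-90). Both contrasts share the estimate of spread of each gene, so this expected count tends to be too low.

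**Figure D4:**
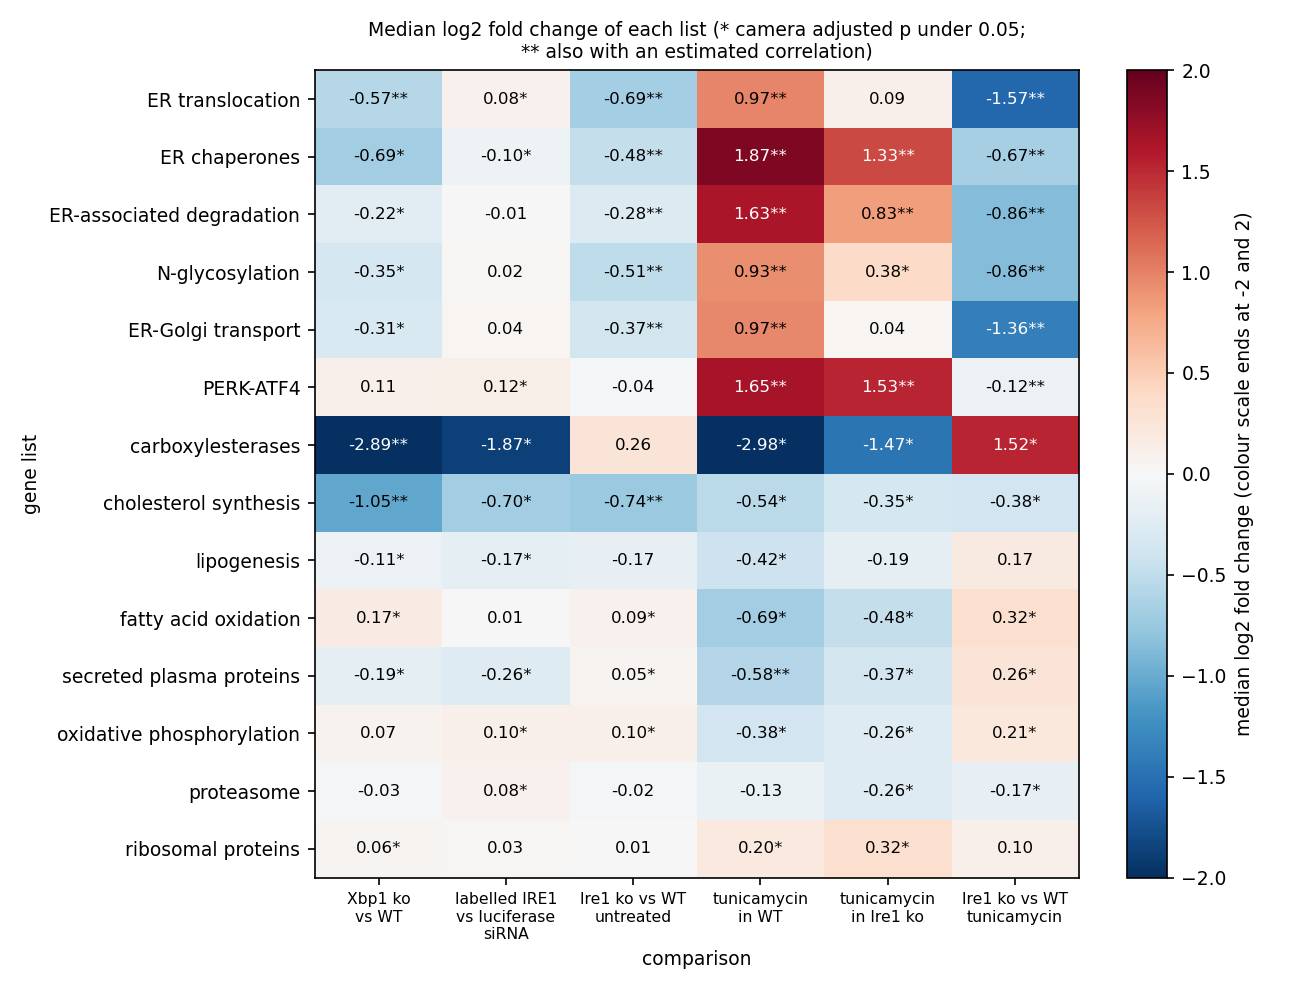
Median log2 fold change (colour, scale limited at its ends) of gene lists (vertical) in 6 comparisons (horizontal). A single asterisk marks a camera adjusted p under 0.05 and a double asterisk a call that also held with an estimated correlation. The ER translocation list has a median of -1.57 in Ire1 ko versus WT after tunicamycin and 0.97 for tunicamycin in WT.

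The overlap of Xbp1 ko with Ire1 ko after tunicamycin was meant to find targets of XBP1, which lack their activator in both. Of 290 genes lower in Xbp1 ko, 96 were among the 1255 lower in Ire1 ko after tunicamycin (26.5 expected among 13748 genes; Fisher's exact p = 8.79e-31). The 12 with the largest changes were Chid1, Tmed3, Dnajb9, Sec11c, Sec61b, Rpn1, Txndc5, Gpr108, Ostc, Creld2, Edem2 and Uggt1. Without single arrays the count lay between 64 (without WT replicate 1) and 104. Another 88 genes were lower in Xbp1 ko and higher in Ire1 ko after tunicamycin (30.9 expected; Fisher's exact p = 1.36e-20), led by Ces1d, Bloc1s1, Ces1g, Tmem238, Retreg3, Dpp7, Hc, Ptprf, Ces1f, Sidt2, Lrp1 and Hgsnat. Of the genes lower in the arrays labelled IRE1 siRNA, 77 were higher in Ire1 ko after tunicamycin (17 expected; Fisher's exact p = 2.5e-33) and 101 fell with tunicamycin in WT (30.7 expected; Fisher's exact p = 2.45e-34). In Ire1 ko after tunicamycin 15 of the same genes were lower (14.6 expected). The genes higher as labelled did not mirror this: 18 were higher (9.61 expected; Fisher's exact p = 0.00627) and 8 lower (8.27 expected; Fisher's exact p = 0.593) in that comparison. Across genes the log2 changes of the siRNA comparison and of Ire1 ko after tunicamycin had a Pearson correlation of -0.066. These overlaps compare groups that share no arrays. Bright genes were called more often, so the expected counts tend to be too low.

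With an estimated correlation 3 of the 14 lists called by camera held in the Xbp1 comparison, 0 of 14 in the siRNA comparison and 6 of 13 in untreated Ire1 ko. For tunicamycin 8 of 22 held in WT and 4 of 17 in Ire1 ko, and 6 of 18 held between the genotypes after tunicamycin and 3 of 15 for the interaction. By fry, which asks only whether a list moves one way, the numbers were 9, 7, 6, 21, 17, 18 and 13. The median of 0 of the 113 called lists changed sign with quantile normalization or a common median over brighter probe sets.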

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

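The tests on Ern1 in the siRNA arrays and on Bcl6, Cish and Onecut1 were chosen after those results were seen, as were the splits for 2 overlaps (104 and 88 genes), while the other splits and the count of called genes near Ern1 were set before their outcome was seen.

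Ern1 was higher, not lower, in the arrays labelled IRE1 siRNA on its only probe set well above the floor. If 1 mislabelled array were the source, an array labelled luciferase would reach the lowest array labelled IRE1, and 0 of the 4 did. Had the siRNA raised Ern1, the arrays labelled luciferase would lie at the level of Xbp1 ko mice without siRNA, but they lay at a log2 difference of -3.004 with no overlap, in mice of another age. An exchange of the labels of the 2 siRNA groups is a candidate explanation: the 88 genes lower in Xbp1 ko and higher in Ire1 ko after tunicamycin, chosen without the siRNA arrays, had a median log2 change of -0.905 as labelled (quartiles -1.41 and -0.522), all 88 below 0. The 96 genes lower in both had a median of -0.021 (quartiles -0.242 and 0.098), and an exchange made before or after hybridisation cannot be told apart from these values.

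In untreated Ire1 ko liver Bcl6 was higher and Cish and Onecut1 were lower than in WT. These 3 genes respond to growth hormone, which is released in pulses in male mice, so the state of the pulse at sampling is a candidate explanation. Across 20 arrays of 5 other groups without tunicamycin, the deviations of Bcl6 and Cish from their group means had a Pearson correlation of -0.514 (permutation p = 0.262; adjusted p = 0.297 over 3 relations) and a Spearman correlation of -0.176 (permutation p = 0.572; adjusted p = 0.858). Without the 2 arrays farthest out the Pearson correlation was -0.052, and Bcl6 with Onecut1 gave -0.668 (permutation p = 0.0587; adjusted p = 0.176) and -0.223 without them, Bcl6 with Socs2 -0.399 (permutation p = 0.297) and 0.22, so the explanation stays open. Strain variants near Ern1 that act on the genes beside them are argued against for these genes by map position alone. Of the 3, 0 lie among the 100 tested genes on each side of Ern1. No intensity could change that outcome, so it is not a test of these data. Other strain differences stay open under conflicting labels.

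Strain variants near Ern1 that act on the genes beside them were also examined for the 143 genes called in untreated Ire1 ko. Of the 200 tested genes nearest to Ern1 0 were called, the outcome set beforehand as going against such variants. All 143 lay among the 14849 elsewhere, so none of them is such a neighbour. That rate gives only 1.93 genes among 200, so a count of 0 decides little. Whether calls are rarer or more frequent near Ern1 cannot be told (Fisher's exact p = 0.269). Variants that act on distant genes and other strain differences stay open.

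Other splits of the same arrays tested whether chance differences between arrays call as many genes. Of 35 splits, 1, the real one, gave as many genes for each comparison of groups. The real and highest other counts were 380 and 30 for Xbp1 ko, 253 and 44 for siRNA, 143 and 41 for untreated Ire1 ko, 5485 and 6 for tunicamycin in WT, 4197 and 1591 for tunicamycin in Ire1 ko, and 2756 and 3 for Ire1 ko after tunicamycin. Chance is unlikely for each of these but not excluded. The share of 1 in 35 is the lowest such splits can give and was not adjusted over the comparisons. Splits that mix the groups also count the group difference as spread, so their low counts are partly built in. For the interaction 4 of 100 drawn splits gave as many genes as the real 1144, the highest other 1772. All 4 kept or wholly reversed the genotype of the 8 tunicamycin arrays, as 5 of the 100 did, and the other 3 mixed the untreated arrays. The count therefore follows the genotype difference after tunicamycin, and these splits do not test the interaction itself. For the joint counts, 1 of 35 splits of the Xbp1 arrays gave as many genes as the real 96 (lower in both Xbp1 ko and Ire1 ko after tunicamycin), 104 (lower in Xbp1 ko and in the arrays labelled IRE1 siRNA) and 88 (lower in Xbp1 ko, higher in Ire1 ko after tunicamycin), with a highest other of 1 each. No other split called more than 30 genes in all, so none could reach these counts, and the splits add nothing to those for Xbp1 ko. For genes lower in Xbp1 ko and higher in the arrays labelled IRE1 siRNA the real count was 0 and the highest other 1. Every split reaches 0 (35 of 35), so the splits decide nothing there, and the count is 104 with the siRNA labels exchanged.

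Single arrays stood apart from the other 3 of their group in 12 of 133 groups of 4 values, where chance gives about 1 in 20. In Xbp1 WT, replicate 2 had a Ces1c intensity of 3735 (next 3213), and replicate 4 had 19.8% of probe sets at 16 or more (next 21.1%) and a 95th percentile of 210 (next 225). In Xbp1 ko, Ces1e was 21 in replicate 4 (next 9) and Ddit3 16 in replicate 1 (next 15). Among the arrays labelled IRE1 siRNA, replicate 4 had 26 for Hgsnat (next 20) and 16 for Ddit3 (next 21). In untreated WT of the Ire1 experiment, replicate 3 had 6 for Atf3 (next 5) and 1195 for Hspa5 (next 901). After tunicamycin, Cav1 was 4 in WT replicate 1 (next 5), Cish 8 in Ire1 ko replicate 3 (next 7) and Onecut1 9 in Ire1 ko replicate 2 (next 7). Several of these are steps of 1 unit at the floor, and the genes examined were chosen after seeing the data.

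The response to tunicamycin differed between WT and Ire1 ko for 1144 genes by the interaction test of limma. The interactions of the named genes were, on the log2 scale, -5.27 for Far1, -4.90 for Bhlha15, -4.74 for Ube2c, -4.01 for Tspyl2, -3.87 for Suco, -3.61 for Ccdc134, -3.60 for Nhsl1 and -3.49 for Kctd7. Positive interactions were 4.04 for Ces1d, 2.78 for Gm2788, 2.75 for Sgk1, 2.45 for Sorbs3, 2.43 for Bloc1s1, 2.35 for Clec2d, 2.30 for Phlda1, 2.25 for Retreg3, 1.48 for Ces1f, 1.33 for Ces1e, 1.12 for Xbp1 and 0.86 for Ces1c.

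Probe sets without exactly 1 gene symbol, 16139 in all and not used above, also changed. The same test called 85 of them in Xbp1 ko, 64 between the siRNA groups, 33 in untreated Ire1 ko, 2136 for tunicamycin in WT, 1503 for tunicamycin in Ire1 ko, 875 for Ire1 ko after tunicamycin and 331 for the interaction.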

How the results depend on the processing

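The common median over brighter probe sets, the filter at an intensity of 16 and the exchange of the siRNA labels were chosen after seeing the data. The other alternatives were planned, but they were extended, after the data were seen, to 2 further overlaps, genes lower in both Xbp1 ko and the arrays labelled IRE1 siRNA and genes lower in Xbp1 ko and higher in Ire1 ko after tunicamycin.

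For the genes named by rule, 10734 of 11236 values under alternatives kept direction and call, 501 kept direction but lost the call, and 444 of 546 results kept both throughout. Ssr4 in Xbp1 ko reversed to 0.025 (adjusted p = 1) without probe sets ending in _x_at or _s_at, where another probe set stands for the gene. For the called lists, 343 of 452 values held and 109 lost the call, of which 83 with an estimated correlation, 22 by fry, 3 with a replicate block and 1 without a filter, and 0 reversed.

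Total counts and overlaps that moved by over 1.5 times, or from 0, were as follows, and the cause was not tested unless the setting states it. With a common median over brighter probe sets, genes lower in both Xbp1 ko and the arrays labelled IRE1 siRNA numbered 167, and those lower in the first and higher in the second 1. With the filter at an intensity of 16, which tests fewer genes, the siRNA comparison gave 398 genes and these overlaps 166 and 1, and with the filter at the array median the latter was 1. Robust eBayes gave 384 genes for siRNA and overlaps of 157 and 1. One fit over all 31 arrays gave 571 genes for Xbp1 ko. The replicate number as a block gave 198 for Xbp1 ko, 44 for siRNA, and overlaps of 46 (Xbp1 ko and Ire1 ko after tunicamycin, both lower), 58 (lower, then higher) and 19 (Xbp1 ko and siRNA as labelled, both lower). Whether the replicate numbers pair the arrays stays open. Pairs with the same number correlated at 0.022 to 0.311 in the Xbp1 arrays, -0.152 to 0.081 in the siRNA arrays and -0.178 to 0.308 in the Ire1 arrays. No correlation was computed for pairs with different numbers. Values were centred within groups, so the covariances over all pairs between 2 groups average 0 by construction. The 4 Xbp1 pairs all lay above 0, while the siRNA and Ire1 pairs lay on both sides of it. At a threshold of at least 2-fold, stricter by construction, the counts in the order of the comparisons were 117, 62, 43, 1950, 1266, 693 and 518, and the same 3 overlaps 19, 17 and 51. With the siRNA labels exchanged, by construction, 104 genes were lower in Xbp1 ko and higher with IRE1 siRNA and 0 lower in both. Counts by direction could move further than totals. Genes higher in Xbp1 ko, 90 in the main fit, numbered 188 with the filter at an intensity of 16 and 178 with robust eBayes. Genes higher in the siRNA comparison as labelled, 91 in the main fit, numbered 170 and 158. In untreated Ire1 ko the 12 higher genes became 25 in one fit over all 31 arrays.

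Leaving out 1 array gave 237 (without WT replicate 1) to 373 genes for Xbp1 ko, 190 to 268 for siRNA, 96 to 147 for untreated Ire1 ko, 5056 to 5234 for tunicamycin in WT, 3554 to 3955 in Ire1 ko, 2337 to 2530 between the genotypes after it and 921 to 1106 for the interaction. Overlaps lay at 0 to 2 (lower in Xbp1 ko, higher in the arrays labelled IRE1 siRNA), 76 to 99 (lower in both), 64 to 104 (lower in Xbp1 ko and in Ire1 ko after tunicamycin) and 67 to 85 (lower, then higher). The planned shift of each array to a common median was not run, because the median was 5 on every array and the shift moves nothing. Signal over background limited the dim genes: of the calls, 43 in the Xbp1 and 40 in the siRNA comparison had no group mean of 16 or more.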

Other observations

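The gene lists in this part, lysosomal genes and antigen presentation on MHC class I, were chosen after the data were seen, so their counts describe these arrays and are no independent test. Their p values were adjusted over these 2 lists, not over the 39, and cannot be set beside those of the other lists. The genes named here were chosen after their values were seen.

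Lysosomal genes were lower in part in Xbp1 ko and in the arrays labelled IRE1 siRNA. Of 41 measured, 9 were lower and 1 higher in Xbp1 ko (11 and 1 adjusted over the list alone), with Lamp1, a membrane protein of lysosomes, at -1.41 (SE 0.09), Gm2a at -1.20 (SE 0.20) and the peptidase Tpp1 at -0.85 (SE 0.06). The camera adjusted p was 0.000166 (adjusted p = 0.0554 with an estimated correlation). In the arrays labelled IRE1 siRNA 7 were lower (9 lower and 2 higher adjusted over the list alone), with Lamp1 at -1.29 (SE 0.07), Gm2a at -1.14 (SE 0.09) and Tpp1 at -1.11 (SE 0.10), and the adjusted p = 0.0846 with an estimated correlation. In untreated Ire1 ko only Ctsl was called, at 0.41. With tunicamycin in WT 30 fell and 2 rose (31 and 3 adjusted over the list alone), Dpp7 at -2.05 (SE 0.18) and Npc1, a cholesterol transporter, at 1.97 (SE 0.17), with an adjusted p = 0.0608 with an estimated correlation. In Ire1 ko 15 fell and 2 rose (17 and 2 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). After tunicamycin 18 were higher and 2 lower in Ire1 ko than in WT (21 and 2 adjusted over the list alone), with Dpp7 at 2.02 (SE 0.18) and Tpp1 at 0.84 (SE 0.14), and the adjusted p = 0.089 with an estimated correlation.

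Of 9 measured genes of antigen presentation on MHC class I, 4 were lower in Xbp1 ko (camera adjusted p = 4.64e-06; adjusted p = 0.0183 with an estimated correlation). They were Tapbp, which loads peptides onto MHC class I, at -1.25 (SE 0.10), H2-T23 at -0.88 (SE 0.13), H2-Q10 at -0.44 (SE 0.06) and H2-K1 at -0.35 (SE 0.06). The 4 lower in the arrays labelled IRE1 siRNA were Tapbp at -1.18 (SE 0.12), H2-T23 at -0.68 (SE 0.06), H2-Q10 at -0.29 (SE 0.04) and H2-K1 at -0.15 (SE 0.03), with 1 also higher adjusted over the list alone and a list median of 0.001 beside a camera direction below 0 (adjusted p = 0.112 with an estimated correlation). In untreated Ire1 ko 0 of the 9 were called by limma (camera adjusted p = 0.258). With tunicamycin in WT 2 rose and 3 fell (camera adjusted p = 0.73). There the paralog Tapbpl rose by 1.93 (SE 0.17) while Tapbp fell by 0.90 (SE 0.12). With tunicamycin in Ire1 ko 2 fell (camera adjusted p = 0.183). After tunicamycin 1 was higher and 2 were lower in Ire1 ko than in WT (camera adjusted p = 0.743).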
